A study of Mus musculus with 3072 samples.

How the data were processed

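Each sample of the series is 1 well of a plate: the labels list 3072 wells in 8 groups of 384, defined by genotype, tissue and age in months. Per the labels, microglia of male mice were sorted as CD11b-positive and DAPI-negative single cells and their cDNA was made with a modified SmartSeq2 protocol, which carries no molecular identifiers. The labels name no animals, so all cells of a group were treated as 1 sample, and plates and lanes as technical parts of it. The deposited count table holds whole-number read counts for 29474 genes and 1878 cells; 1878 of its columns matched a sample by name and 0 did not. The deposited normalised table holds natural log values for 21199 genes and 1879 cells, equal to ln(1 + 10000 times the count over the total of the cell) within 6.2e-15, with 1 cell that has no counts; it was used for this check alone. Per the submitters' processing notes, which give names without roles, STAR 2.5.2, featureCounts 1.5.1, Seurat 2.3.1 and the build mm10 were used. Which reads were counted for overlapping genes, and whether strand was used, is not given in the sources used here, so overlapping genes, antisense genes and near-identical paralogs can share reads.

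The labels give a read total and a gene number for 1713 of the cells with counts, both equal to the table's own in 1713 cells, and these cells were used. A further 165 APP/PS1-ApoeKO cortex cells of 1 lane, for which the labels give no depth, entered an alternative. Counts were at hand for 6 of the 8 groups; the APP/PS1 groups at 18 months were not analysed here. The comparisons planned against them were made against the 17-month groups, so that the knockout contrasts in APP/PS1 differ in lane and by 1 month of age, no ratio between 17 and 18 months could serve as a yardstick, and the tests planned on 6 and 5 sums were made on 4. The lanes were 8 and the plate numbers used 4. These numbers did not follow the plate in a well's title: wells of 1 titled plate were spread over them by well column. A plate below is therefore a part of a group's wells and not a physical plate. Such a part can mix wells of several titled plates and of both lanes. C57BL/6 and C57BL/6-ApoeKO shared both their lanes, as did APP/PS1 cortex and hippocampus. The APP/PS1-ApoeKO tissues shared no lane with another group analysed here. The labels also place wells of APP/PS1 cortex at 18 months, not analysed here, in a lane of APP/PS1-ApoeKO cortex. The APP/PS1-ApoeKO cortex cells used came from 1 lane and 2 of the well parts called plates. No cells were identical (0 pairs), and the highest correlation over all pairs of cells was 0.604.

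Reads per cell ranged from 190664 to 981052 in APP/PS1 cortex, 71761 to 999128 in APP/PS1 hippocampus, 125934 to 769489 in APP/PS1-ApoeKO cortex, 90640 to 995057 in APP/PS1-ApoeKO hippocampus, 116605 to 1320640 in C57BL/6 and 68354 to 1106724 in C57BL/6-ApoeKO cortex. Median genes per cell were 2218, 2131, 2105, 2107, 2265 and 2246 in that order, and the median share of ribosomal RNA reads was 11.8%, 10.9%, 6.35%, 9.50%, 8.39% and 8.62%. A gene without reads in a group was given a floor of 3 reads over the group, which is between 0.0124 RPM (C57BL/6) and 0.0401 RPM (APP/PS1-ApoeKO cortex). Coordinates are from GENCODE on GRCm38, the assembly of mm10.

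Gene lists, named genes, tests and alternatives were fixed before the data were examined, except where stated. The 27 lists hold 301 genes, 278 of them with reads: homeostatic, activated (plaque-associated) and interferon-response microglia, cell cycle, MHC class I and II, border-associated macrophage, monocyte, neutrophil, T or NK cell, B cell, neuron, astrocyte, oligodendrocyte, endothelial or mural cell, immediate early and dissociation, inflammatory cytokines, lipid transport and efflux, cholesterol synthesis, lysosome, complement, Alzheimer risk loci, phagocytic receptors, TGF-beta signalling, glycolysis and respiratory chain, with 1 list of 4 check genes that is not reported here. Named were these list members and, for each comparison of 1 sum against 1, the 10 higher and 10 lower genes by log2 ratio (0.5 RPM added) with at least 20 RPM and reads in at least 10% of cells in 1 of the groups. The rule also took, for each tested contrast, the 10 largest changes in each direction among genes past an adjusted p of 0.05, of which there were 0. Predicted genes, pseudogenes marked as such by name, mitochondrial genes and spike-ins were counted and not named. The part of the rule that needed 18-month APP/PS1 cells could not be applied. Genes named outside the rule were chosen after their values were seen: Gm11942 and Gm15772, called in a fit of 6 sums.

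Counts were summed over the cells of a group. In the 7 comparisons of 1 sum against 1, ratios of RPM had exact 95% intervals for counts, and no p-value was computed. A list's members had at least 1 RPM on average over the sums, or 12703 genes in all; lists of at least 3 such members were measured (21 lists), and the median log2 ratio was placed among 10000 random lists of the same size, matched in 20 bins of expression. In data simulated as independent Poisson counts, 200 of 200 genes changed 2-fold were estimated within 20% of that fold. There 93.8% of the intervals held the true ratio, and 2 of 40 unchanged lists lay outside the middle 95%. Such data hold no dependent reads, no spread between cells or mice and no correlated genes. These values therefore check the computation and not how the intervals or percentiles behave in the real sums.

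In 3 contrasts the sums were tested with edgeR 4.0.16 (quasi-likelihood F test, two-sided, TMM, filterByExpr, Benjamini-Hochberg adjustment): hippocampus against cortex with genotype as a block (APP/PS1 and APP/PS1-ApoeKO), and amyloid and Apoe knockout as additive terms over the 4 cortex sums. Each fit had 4 sums and 1 residual degree of freedom, and the p-values measure the spread between these sums alone, which holds any interaction. The SE beside an edgeR log2 fold change is its absolute value over the square root of the F statistic. It was derived from the test and not estimated directly. Lists were tested with camera (limma 3.58.1) with a preset correlation of 0.01, and again with an estimated correlation, with which 0 lists were called in all 3 contrasts. On counts simulated at the spread of the real sums, edgeR recovered 10, 22 and 37 of 67, 67 and 66 genes changed 2-, 4- and 8-fold for tissue, 6, 26 and 38 for amyloid, and 6, 23 and 30 for Apoe, with 15 false calls of 16352 unchanged genes for tissue, and 29 and 18 of 16999. DESeq2 recovered 45, 43 and 43 genes changed 8-fold and made 200, 243 and 282 false calls. A simulated list of 20 changed genes was called with the preset correlation in each contrast and had an adjusted p of 0.979, 0.783 and 0.985 with an estimated one. Genes were drawn independently in these data. They therefore do not show whether the preset correlation holds for lists of genes that vary together.

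Cells were clustered with scanpy 1.11.5 and leidenalg 0.10.2 (natural log of 1 plus reads per 10000, 2000 variable genes without Apoe and the other check genes, 20 components, 15 neighbours, resolution 0.8), which gave 8 clusters. A cluster was named from at least 3 fixed markers among its 10 leading genes by fold in at least 25% of its cells, and otherwise as homeostatic-like where at least 10 homeostatic markers were each read in at least 50% of its cells and fewer than 3 of its 10 leading genes were predicted, ribosomal or mitochondrial by name. The homeostatic-like rule was not part of the plan. Cluster 5 (110 cells; led by Lpl, Cst7, Ank, Clec7a and Apoe) was activated-like and cluster 6 (59 cells; led by Ifit3, Ifit2 and Irf7, with 3 MHC class II genes among its 10 leaders) interferon-response-like. The size of cluster 6 was not compared between groups, because no such cluster was found at resolution 0.4. Clusters 0, 1, 3, 4 and 7 were homeostatic-like: clusters 0 and 3 held most such cells of the knockout groups, cluster 1 those of APP/PS1 and cluster 4 with cluster 1 those of C57BL/6. Cluster 2 (241 cells, 108 of them from C57BL/6 and 69 from C57BL/6-ApoeKO, median 442943 reads) stayed unnamed, with 5 such genes among its leaders. No doublet caller was run on single sorted wells. Shares have exact (Clopper-Pearson) binomial 95% intervals, and differences of shares Newcombe 95% intervals from Wilson bounds. For the test on the mix of states, clusters made without activated markers and shared knockout genes, with at least 10 cells of both groups, were weighted by the smaller of the 2 groups' fractions, and the interval is from 2000 bootstrap draws of cells and genes. A first form of this test, in homeostatic-like cells alone, was dropped because those clusters are led by genes under test.

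The alternatives were RLE size factors, no filter on low counts, limma on cells scaled to equal totals, DESeq2 1.42.0, homeostatic-like cells alone, 5 RPM added in place of 0.5, each plate left out, other resolutions and numbers of components, thinning and a score. Added after seeing the data were all cells of the table, a fit of all 6 sums, reads without ribosomal and mitochondrial RNA, and clustering without activated markers and shared knockout genes. Leaving out a collection, a coefficient per genotype and a fit without the 17-month sum would leave 0 residual degrees of freedom and gave no test; microglia-like cells alone equal the cells used, since no cluster was named as another cell type; activated-like cells alone were too few. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and R 4.3.3 were used.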

Results

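Microglia, the resident macrophages of the brain, were sorted as single live CD11b-positive cells from male mice, and the polyadenylated RNA of each cell was read with a modified SmartSeq2 protocol. APP/PS1 mice carry mutant transgenes and form amyloid plaques with age. The series asked how the loss of Apoe, the gene of the lipid carrier apolipoprotein E, bears on the microglial response to these plaques. Read counts were analysed for 1713 cells of 6 groups: APP/PS1 cortex (311 cells, 188282466 reads) and hippocampus (273 cells, 156047722 reads) at 17 months, APP/PS1-ApoeKO cortex (169 cells, 74767907 reads) and hippocampus (321 cells, 151578978 reads) at 18 months, and the cortex of C57BL/6 (326 cells, 241536311 reads) and C57BL/6-ApoeKO mice (313 cells, 198704815 reads) at 18 months. The 2 APP/PS1 groups at 18 months were not analysed here. The median cell held between 442917 reads (APP/PS1-ApoeKO hippocampus) and 765703 reads (C57BL/6 cortex). The labels name no animals, so each group was 1 sample. Ratios between 2 groups therefore had no replicate check, and their 95% intervals treated each read as an independent count. Reads without molecular identifiers are not independent molecules, so these intervals are too narrow even for counting error. They also leave out the spread between cells and between mice. Levels are in RPM, the reads of a gene over all reads of the summed cells of a group. A plate named below is a part of a group's wells and not a physical plate.

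Apoe was the targeted gene and was read at 13406 RPM in APP/PS1 cortex and 11919 RPM in APP/PS1 hippocampus. It was read at 0.067 RPM in APP/PS1-ApoeKO cortex (5 reads), 0.745 RPM in APP/PS1-ApoeKO hippocampus (113 reads) and 2.96 RPM in C57BL/6-ApoeKO cortex (589 reads). C57BL/6 cortex lay between, at 485 RPM. Apoe lies on chromosome 7 from 19696109 to 19699188 in GRCm38. With each cell thinned to 100000 reads, the share of cells with an Apoe read was 88.4% in APP/PS1 cortex (95% interval 84.3 to 91.8), 82.0% in APP/PS1 hippocampus, 28.8% in C57BL/6 cortex (24 to 34.1), and 1.18%, 0.940% and 0.974% in the 3 knockout groups in the order above. Without thinning these shares were 92.3%, 86.1%, 31.6%, 2.37%, 0.935% and 1.60%. The knockout cells held a few cells with most of the Apoe reads: 582 of 589 reads in C57BL/6-ApoeKO were in 2 cells, and 108 of 113 in APP/PS1-ApoeKO hippocampus were in 2 cells. App was read at 80.5, 110, 114 and 110 RPM in the 4 transgenic groups in the order given and at 68.9 and 86.8 RPM in C57BL/6 and C57BL/6-ApoeKO cortex. Prnp, whose promoter often drives such transgenes, was read at 14.2, 5.83, 6.82 and 3.80 RPM against 1.10 and 3.69 RPM.

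**Figure D1:**
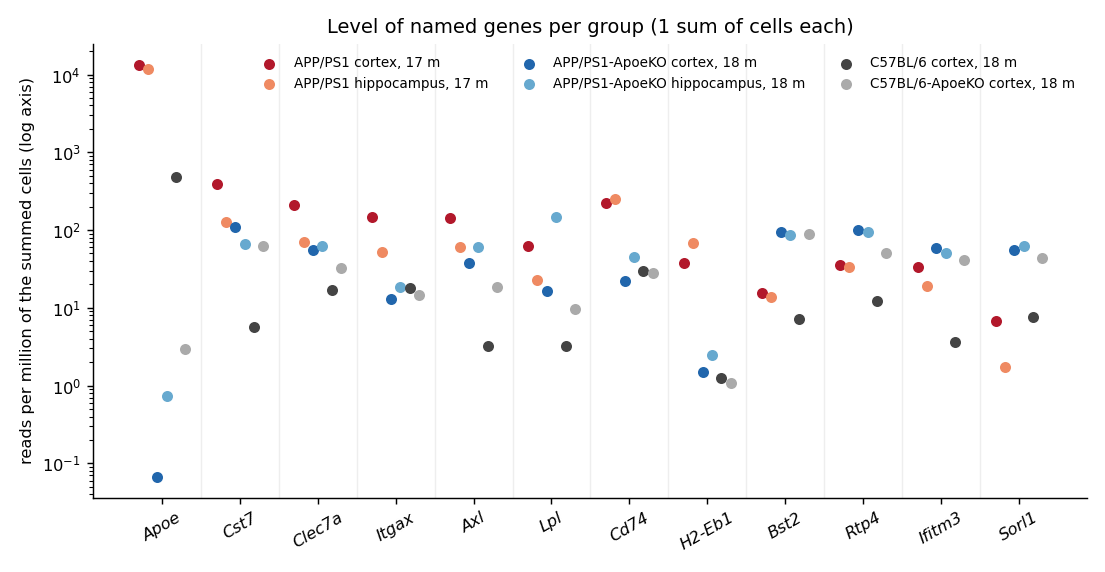
RPM (log axis) of 12 named genes in the 6 groups; each point is 1 sum of the cells of a group, with no replicates. Apoe lies at 13406 RPM in APP/PS1 cortex and at 0.067 RPM in APP/PS1-ApoeKO cortex, and Bst2 lies at 93.8, 86.8 and 88.5 RPM in the 3 knockout groups.

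The effect of Apoe loss on microglia exposed to amyloid was read from APP/PS1-ApoeKO against APP/PS1 mice. In cortex the activated, plaque-associated genes were lower in the knockout: 14 of 16 measured members lay below a ratio of 1, 10 of them at least 2-fold. The median share of ribosomal RNA reads was also lower in the knockout, at 6.35% against 11.8%. Cst7, an inhibitor of lysosomal cathepsins, was 3.55-fold lower (387 against 109 RPM). Itgax, the integrin CD11c, was 11.2-fold lower, the beta-glucan receptor Clec7a 3.75-fold, and the receptor kinase Axl 3.74-fold lower. Fabp5, a fatty acid binding protein, was 66.4-fold lower, and Spp1, osteopontin, was read at 19.8 RPM in APP/PS1 and had 0 reads in the knockout. MHC class II genes were also lower, in 5 of 6 members: H2-Eb1 25.7-fold and the invariant chain Cd74 10.1-fold, while H2-DMa, which loads peptides, was 1.56-fold higher (1.53 to 1.59).

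In hippocampus the same knockout contrast left the activated genes closer together, with 12 of 16 members below a ratio of 1 and 5 at least 2-fold lower. Itgax was 2.79-fold lower and Cst7 1.92-fold lower, Clec7a 1.15-fold lower, and Axl stood at a ratio of 0.997 (0.968 to 1.03). Lpl, lipoprotein lipase, was 6.44-fold higher (6.21 to 6.67) in the knockout, although it was read in 4.0% of the knockout cells and 4.4% of the APP/PS1 cells. MHC class II was lower here too, in 4 of 6 members, with H2-Eb1 27.6-fold and Cd74 5.51-fold (5.37 to 5.65) lower. The other 2 members were higher, 1 of them at least 2-fold. Over all groups, H2-Eb1 was read in 28.8% of the cells of the interferon-response-like cluster and 2.48% of all other cells. Its ratios in both tissues therefore rest on few cells. Inflammatory cytokine genes went the other way in the 2 tissues. In hippocampus 8 of 10 were higher in the knockout, among them the chemokines Ccl3 (4.27-fold, 4.13 to 4.41) and Ccl4 (5.20-fold, 4.94 to 5.47). In cortex 6 of 10 were lower, with Ccl4 3.15-fold and Il1b 42.8-fold lower.

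As a list, the activated genes had a median log2 ratio of -1.89 in cortex, below the middle 95% of 10000 random lists matched on expression (-0.20 to 0.55, percentile 0), and -0.23 in hippocampus (percentile 2.39). MHC class II stood at -2.21 (percentile 0; -0.12 in homeostatic-like cells alone) and -1.64 (percentile 0; -0.67 in homeostatic-like cells alone), and cytokines at -0.56 (percentile 0.23; 0.58 in homeostatic-like cells alone) and 0.94 (percentile 99.97). The cytokine median in hippocampus ranged from 0.28 to 1.14 over the alternatives. Over pairs of the well parts called plates, the MHC class II median had an SD of 0.549 in cortex and 1.25 in hippocampus. Interferon-response genes were higher in 12 of 16 members in knockout cortex and 11 of 16 in hippocampus, with medians of 0.55 (-0.16 without plate 4) and 0.44 inside the random range. Genes without reads in 1 group, 3 of the activated genes in each tissue, did not set these medians: with such genes held at 3 reads over the group they were -1.90 and -0.23. Lysosomal genes, such as the protease Ctsd (1.47-fold lower), had a median of -0.23 in cortex (14 of 18 lower, percentile 0.22; -0.08 in homeostatic-like cells alone) and 0.01 in hippocampus (percentile 21.4). Lipid transport genes had medians of -0.29 (10 of 14 lower, percentile 0.06) and -0.17 (percentile 2.31), but the cholesterol exporters Abca1 (1.73-fold, 1.71 to 1.74) and Abcg1 (1.88-fold, 1.85 to 1.91) were higher in knockout cortex. Glycolysis genes had a median of -0.23 in cortex (10 of 12 lower, percentile 0.46) and 0.13 in hippocampus. Homeostatic microglial genes, such as the purine receptor P2ry12 (1.15-fold higher in cortex), had medians of 0.16 in both tissues, inside the random range. Of 6090 genes considered in cortex, 538 were at least 2-fold higher and 184 at least 2-fold lower; in hippocampus these were 254 and 159 of 5914. With the 165 further cells of 1 lane that the labels give no depth for, 119 genes were at least 2-fold lower in cortex. The median over all genes was 0.19 in cortex and 0.07 in hippocampus, and the random lists carry the same shift. The groups of this contrast came from different sequencing lanes and differed by 1 month in age, so genotype, lane and age cannot be told apart in it. In homeostatic-like cells alone, held mostly by clusters 0 and 3 in the knockout groups and by cluster 1 in APP/PS1, the activated median was -0.001 in cortex and 0.19 in hippocampus. These cells leave out the unnamed, the activated-like and the interferon-response-like clusters. Smaller medians of the genes that lead the activated-like and interferon-response-like clusters therefore follow from the choice of cells.

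Apoe loss without amyloid was read in C57BL/6-ApoeKO against C57BL/6 cortex, which shared their lanes. Interferon-response genes were higher in the knockout, 15 of 16 above a ratio of 1 and 11 at least 2-fold. Bst2, tetherin, which holds budding virus at the cell surface, was 12.3-fold higher (11.7 to 12.9), Ifitm3, which blocks viral entry, 11.3-fold (10.5 to 12.1), Ifit3 5.66-fold (5.27 to 6.08) and Rtp4 4.06-fold (3.90 to 4.23). The activated genes did not lie lower: 11 of 16 were higher in the knockout, with Cst7 10.9-fold (10.3 to 11.5), Axl 5.69-fold (5.26 to 6.15) and Clec7a 1.93-fold (1.85 to 2.01) higher, and Itgax 1.23-fold lower. Glycolysis genes were higher in 10 of 12, led by Aldoa, the aldolase (2.39-fold, 2.36 to 2.42). The C57BL/6 cells were also apart in genes of no fixed list. Spint1, a serine protease inhibitor, had 0 reads in C57BL/6 and was at least 19347-fold higher in the knockout, taking the floor as 3 reads over the group, and Shroom4 was at least 3469-fold lower in the knockout.

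The interferon list had a median log2 ratio of 1.97 (percentile 100; 1.23 and 1.77 within the 2 lanes, 0.91 in homeostatic-like cells, held mostly by cluster 0 in the knockout and by clusters 4 and 1 in C57BL/6), the activated list 0.41 (percentile 99.5; 0.29 and 0.13 within lanes, 0.09 without plate 1) and glycolysis 0.42 (percentile 100; 0.61 and 0.31). MHC class I, such as the heavy chain H2-K1 (1.67-fold higher), stood at 0.35 (8 of 10 higher, percentile 99.4), MHC class II at 0.01 (percentile 43.3), cytokines at -0.49 (7 of 10 lower, percentile 0.29; 0.33 without plate 3) and homeostatic genes at 0.01. With 3 reads as the floor the interferon median was 2.05. Of 5998 genes, 151 were at least 2-fold higher and 122 at least 2-fold lower. The knockout ratios in cortex were further apart between APP/PS1 and C57BL/6 than in random lists for the activated genes (median difference -2.98 log2, percentile 0), MHC class II (-2.65, percentile 0), glycolysis (-0.76, percentile 0), interferon response (-0.60, percentile 0.39) and lysosome (-0.37, percentile 0.02). That difference between groups was not tested.

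**Figure D2:**
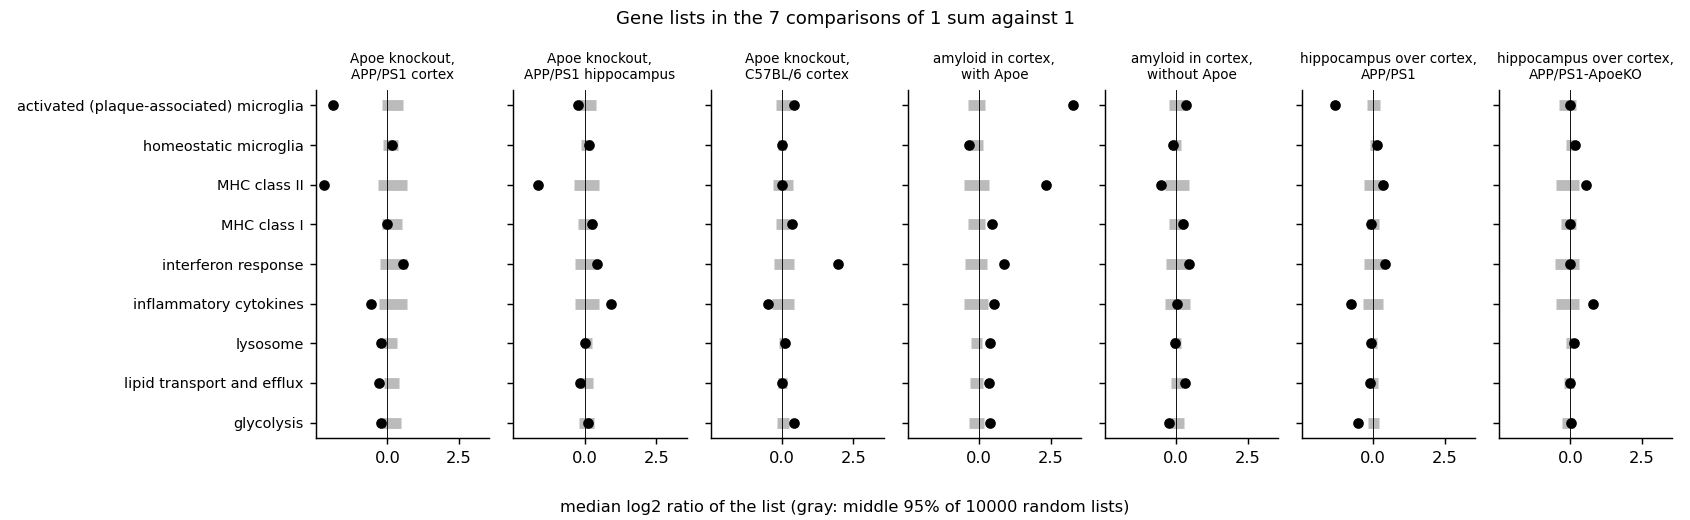
Median log2 ratio of 9 gene lists in the 7 comparisons of 1 sum against 1 (points), with the middle 95% of 10000 random lists matched on expression (gray bars). The activated list stands at -1.89 for the Apoe knockout in APP/PS1 cortex, at 0.41 in C57BL/6 cortex and at 3.29 for amyloid in cortex with Apoe.

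The Apoe knockout contrast was tested over the 4 cortex sums with amyloid as an additive term. Bst2 (log2 fold change 2.96, SE 0.41, adjusted p = 0.919), Sorl1, a sorting receptor of the amyloid precursor (2.61, SE 0.32, adjusted p = 0.919), and Trim12a, of a family of antiviral proteins (12.64, SE 0.64, adjusted p = 0.461), had higher estimates in the knockouts, and Apoe a lower one (-11.49, SE 3.52, adjusted p = 0.919). The quasi-likelihood test of edgeR called 0 of 17199 genes, while DESeq2 called 548 (266 higher, 282 lower). By edgeR 859 genes had an unadjusted p under 0.05, about as many as that limit passes with no effect. Adjusted over the list alone, 1 of 16 interferon genes (Bst2, adjusted p = 0.0366) and 1 of 21 Alzheimer risk genes (Sorl1, adjusted p = 0.0309) passed. For tissue, amyloid and Apoe this was tried on 23, 24 and 24 lists with no adjustment over lists. A few passes can arise from so many tries with no effect. The interferon list rose by camera (median log2 fold change 0.91, 15 of 16 positive, adjusted p = 4.68e-05; adjusted p = 0.958 with an estimated correlation). The activated list fell (-0.31, 11 of 14 negative, adjusted p = 0.0202; adjusted p = 0.958 with an estimated correlation). The activated median joined a negative ratio in APP/PS1 with a positive one in C57BL/6. The 4 sums left 1 residual degree of freedom. Simulated at the spread of these sums, edgeR recovered 30 of 66 genes changed 8-fold and 6 of 67 changed 2-fold, and a simulated changed list was not called with an estimated correlation (adjusted p = 0.985). The genes of that list were drawn independently, so it does not check the preset correlation for real lists. In a fit of all 6 sums, edgeR called 5 genes for the knockout: Trim12a (log2 fold change 12.52, adjusted p = 0.0242) and Scoc (3.98, adjusted p = 0.0326) rose, and Rps3a3 (-9.10, adjusted p = 0.0242), Gm11942 (-8.17, adjusted p = 0.0326) and Gm15772 (-6.49, adjusted p = 0.0446) fell. This fit and the last 2 names were chosen after their values were seen. Rps3a3 is annotated as a processed pseudogene, so its reads can be shared with near-identical copies.

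A set of genes was apart in the same direction in all 3 knockout comparisons, in APP/PS1 cortex, APP/PS1 hippocampus and C57BL/6 cortex, which share no library. Apart from Apoe itself, 47 genes were at least 2-fold higher and 30 at least 2-fold lower in each, of 6660 considered. Independent lists would share 0.975, but these comparisons are not independent. APP/PS1 cortex and hippocampus share a line and lanes, the APP/PS1-ApoeKO tissues share a line, and each comparison sets a knockout line against another line. Differences between lines can recur in all 3, so 0.975 is not the number expected without an effect of Apoe. Trim12a (chromosome 7, 104299894 to 104315466), with 2, 1 and 1 reads in the 3 groups with Apoe, was 4884-fold (1351 to 40344) higher in APP/PS1 cortex, and Trim30d, 50.4-fold higher there and 7.87-fold in APP/PS1 hippocampus, lies at 104470014 to 104507849. Scoc (chromosome 8, 83430084 to 83458391) was 19.4-fold (18.4 to 20.4) and 13-fold higher in APP/PS1 and C57BL/6 cortex, and its neighbour Clgn (83389867 to 83428552), a chaperone known from testis, at least 2332-fold and 587-fold (20-fold in APP/PS1 hippocampus). Bst2 (chromosome 8, 71534255 to 71537456) was 6.11-fold (5.85 to 6.39), 6.32-fold (6.04 to 6.62) and 12.3-fold higher in the 3 comparisons, and Sorl1 (chromosome 9, 41964720 to 42124297) 8.19-fold (7.69 to 8.72), 35.5-fold (31.5 to 40.3) and 5.67-fold (5.40 to 5.97). Hpgd, which degrades prostaglandins, was 45.5-fold (43.6 to 47.5) and 36.6-fold higher in APP/PS1 cortex and hippocampus and 9.45-fold in C57BL/6 cortex. Fcrls, a homeostatic microglial gene, was 5.26-fold, 4.31-fold and 2.41-fold higher. Among the lower genes were Colec12, a scavenger receptor (at least 1767-fold and at least 3403-fold in APP/PS1 cortex and hippocampus) and Hbegf, a growth factor (23.8-fold and 14.0-fold, and 7.06-fold in C57BL/6 cortex). Of the 77 genes, 13 have the name of a predicted gene or pseudogene. This count goes by name alone: some of the 13 are annotated as protein coding, and Rps3a3 is not among them. Reads of the Trim, Slfn and H2 families can be shared between paralogs.

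**Figure D3:**
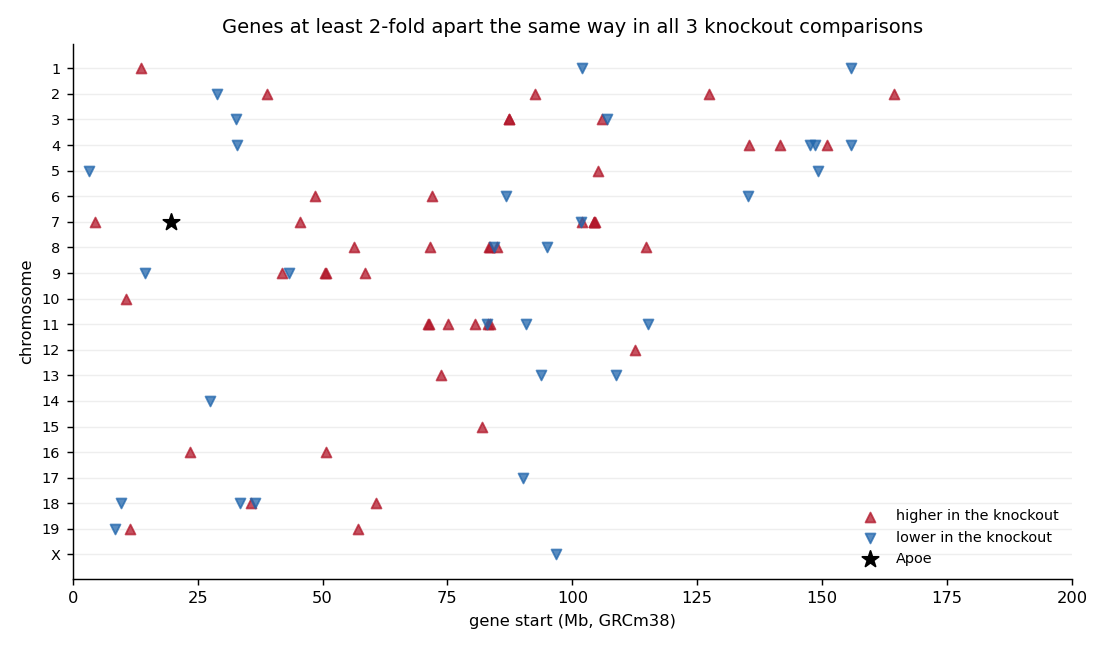
Chromosome and start position (Mb, GRCm38) of the 76 genes with a position that were at least 2-fold apart the same way in all 3 knockout comparisons; upward triangles are higher and downward triangles lower in the knockout, and the star marks Apoe. Chromosomes 7, 8 and 11 hold 7, 8 and 9 of them.

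Amyloid in cortex was compared with Apoe (APP/PS1 at 17 months against C57BL/6 at 18 months) and without it (APP/PS1-ApoeKO against C57BL/6-ApoeKO, both at 18 months). The median share of ribosomal RNA reads was 11.8% against 8.39% with Apoe and 6.35% against 8.62% without it. With Apoe, all 16 activated genes were higher in APP/PS1, 12 at least 2-fold. Cst7 was 68.6-fold higher (65.0 to 72.4), Axl 43.4-fold (40.5 to 46.7), Lpl 18.9-fold (17.6 to 20.4), Clec7a 12.3-fold (11.9 to 12.7) and Itgax 8.13-fold (7.87 to 8.40), and Apoe itself was 27.6-fold higher (27.5 to 27.8). Igf1, a growth factor, was read at 34.8 RPM in APP/PS1 and had 0 reads in C57BL/6. Without Apoe, 10 of 16 were higher and 3 at least 2-fold: Axl 2.04-fold (1.94 to 2.15), Csf1, a ligand of the microglial survival receptor, 2.09-fold (1.94 to 2.26), and Igf1, read at 2.47 RPM against 0 reads. Cst7 was 1.77-fold (1.72 to 1.82) and Clec7a 1.71-fold (1.64 to 1.77) higher.

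Other gene groups were compared in the same way with and without Apoe. MHC class II was higher in 4 of 6 members, with H2-Eb1 30.3-fold (27.0 to 34) and Cd74 7.67-fold (7.48 to 7.87) higher and H2-DMa 2.52-fold lower; without Apoe 1 of 6 was higher and Cd74 was 1.26-fold lower. Lysosomal genes were higher in 15 of 18 with Apoe, such as Ctsd (1.67-fold, 1.67 to 1.68), and in 8 of 18 without. Glycolysis genes were higher in 12 of 12 with Apoe, such as Slc2a1, a glucose transporter (1.61-fold, 1.58 to 1.65), and in 1 of 12 without, where Gapdh was 1.73-fold lower. Interferon genes were higher in 14 of 16 with Apoe, among them Ifitm3 (9.28-fold, 8.65 to 9.97), and in 13 of 16 without, among them Rtp4 (2.00-fold, 1.94 to 2.06). Homeostatic genes were lower in 15 of 15 with Apoe, with P2ry12 1.36-fold and Olfml3 1.60-fold lower, and in 13 of 15 without.

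The median log2 ratios with Apoe were 3.29 for the activated list (3.32 with the floor of 3 reads, 1.17 in homeostatic-like cells, held mostly by cluster 1 in APP/PS1 and by clusters 1 and 4 in C57BL/6), 2.33 for MHC class II (0.26 in the same homeostatic-like cells), 0.88 for interferon response, 0.45 for MHC class I, 0.40 for glycolysis (0.09 in those cells), 0.39 for lysosome (0.13 in those cells), 0.34 for lipid transport, 0.53 for cytokines (-0.02 without plate 1) and -0.34 for homeostatic genes, all outside the middle 95% of random lists. Without Apoe they were 0.35 for the activated list (percentile 97.3, inside that range; 0.59 with the floor, 0.11 without plate 3), -0.53 for MHC class II (percentile 0.49), 0.44 for interferon response (inside; -0.03 without plate 4), 0.31 for lipid transport (percentile 99.5), -0.25 for glycolysis (percentile 0.57) and -2.87 for the cell cycle (percentile 0.02), a list read in few cells. With Apoe 140 of 6009 genes were at least 2-fold higher and 235 lower; without it 219 of 6050 were higher and 133 lower (108 and 65 with the 165 further cells). With the floor of 3 reads the cell cycle median without Apoe was -5.75, as 2 of its members had no reads in 1 group. The difference between the settings with and without Apoe was not tested. The transgenic and non-transgenic groups were sequenced in different lanes, so amyloid and lane cannot be told apart. The C57BL/6 group is the control here and in the C57BL/6 knockout contrast, so its own departures enter both with the same sign. Of 139 genes at least 2-fold higher in APP/PS1 than in C57BL/6, 111 were also higher and 28 lower in C57BL/6-ApoeKO than in C57BL/6. APP/PS1 cortex enters this contrast and the knockout contrast in APP/PS1 with opposite sign, so opposite signs of these are not independent.

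Tested over the same 4 cortex sums with Apoe as an additive term, edgeR called 0 of 17199 genes for amyloid, and DESeq2 called 301 (145 higher, 156 lower). By edgeR 617 genes had an unadjusted p under 0.05, fewer than that limit passes with no effect. The activated list rose by camera (median log2 fold change 1.79, 14 of 14 positive, adjusted p = 2.95e-09; adjusted p = 0.829 with an estimated correlation), with Cst7 at 3.47 (SE 1.87, edgeR adjusted p = 1) and Clec7a at 2.21 (SE 0.91, edgeR adjusted p = 1). Adjusted over the list alone, 1 of 14 activated genes (Igf1, adjusted p = 0.0262) and 1 of 6 MHC class II genes (H2-DMa, lower, adjusted p = 0.0395) passed. With 24 lists tried here and no adjustment over lists, such passes can arise with no effect. The homeostatic list fell (-0.15, 15 of 15 negative, adjusted p = 9.99e-06; adjusted p = 0.829 with an estimated correlation). The lists that rose, each with adjusted p = 0.829 with an estimated correlation, were lipid transport (0.37, 12 of 15 positive, adjusted p = 2.85e-04), MHC class I (0.41, 9 of 10, adjusted p = 2.47e-03), interferon response (0.88, 14 of 16, adjusted p = 6.25e-03), lysosome (0.16, 13 of 18, adjusted p = 6.75e-03) and cholesterol synthesis (0.31, 13 of 18, adjusted p = 0.0378). The cell cycle (-3.29, 8 of 10 negative, adjusted p = 6.75e-03) and B cell lists (-0.55, 3 of 3 negative, adjusted p = 0.0378) fell, both with adjusted p = 0.829 with an estimated correlation. In simulated data edgeR recovered 38 of 66 genes changed 8-fold for this contrast.

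Genes that were at least 2-fold higher in APP/PS1 than in C57BL/6 cortex, 139 in number without Apoe itself, were then read in hippocampus, in libraries not used to choose them but from the same mouse line and lanes as the APP/PS1 cortex. In APP/PS1-ApoeKO hippocampus 84 of them were lower and 55 higher than in APP/PS1 hippocampus, with a median of -0.24 log2 (random lists -0.04 to 0.16, percentile 0); 35 were at least 2-fold lower, among them Itgax, and 6 at least 2-fold higher, among them Lpl. In APP/PS1-ApoeKO over C57BL/6-ApoeKO cortex 84 were higher, 55 lower, and the median was 0.19 (percentile 99.6). The 45 genes at least 3-fold higher had a median of -0.53 in hippocampus and of 0.19 in that cortex comparison, there inside the random range (percentile 91.3).

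Hippocampus was compared with cortex within APP/PS1, in shared lanes, and within APP/PS1-ApoeKO, where the tissues were in different lanes. In APP/PS1 the activated genes were lower in hippocampus in 15 of 16 members, 10 at least 2-fold. Astrocyte markers were higher (median log2 ratio 1.91, 3 of 5 at least 2-fold), but their median was 0.97 in 1 lane and 0.07 in the other. Csf1 was 3.91-fold (3.64 to 4.20), Cst7 3.03-fold (2.98 to 3.07), Clec7a 2.92-fold and Itgax 2.82-fold lower. Glycolysis genes were lower in 11 of 12, such as Tpi1, triose phosphate isomerase (1.91-fold), and 7 of 10 cytokine genes were lower, with Il1b 8.28-fold and Ccl4 2.75-fold lower. The transcription factor Sox4 was 5.25-fold (4.86 to 5.68) higher in hippocampus, and Srebf2, a regulator of cholesterol synthesis, was 3.53-fold (3.34 to 3.74) lower. In APP/PS1-ApoeKO 8 of 16 activated genes were higher in hippocampus, Cst7 was 1.64-fold lower and Lpl 9.04-fold (8.53 to 9.58) higher. Cytokine genes were higher there in 7 of 10, with Ccl4 5.95-fold (5.52 to 6.41) and Ccl3 2.70-fold (2.61 to 2.81).

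The activated list had a median log2 ratio of -1.33 in APP/PS1 (percentile 0; -1.36 and -0.67 within the 2 lanes, -0.52 in homeostatic-like cells) and 0.002 in APP/PS1-ApoeKO (percentile 76.0). Glycolysis stood at -0.53 (percentile 0; -0.59 and -0.48 within lanes) and 0.02, cytokines at -0.77 (percentile 0.02; -0.30 and -0.80 within lanes) and 0.79 (percentile 100; -0.16 without plate 1), MHC class II at 0.35 (percentile 97.7; 0.49 and -0.12 within lanes, -0.19 in homeostatic-like cells) and 0.54 (percentile 99.9; -0.07 in homeostatic-like cells, held mostly by clusters 0 and 3 in APP/PS1-ApoeKO and by cluster 1 in APP/PS1), and homeostatic genes at 0.12 (percentile 95.8) and 0.18 (percentile 99.5). The interferon median of 0.40 in APP/PS1 (percentile 98.4) was 0.52 in 1 lane and -0.25 in the other. The difference between the genotypes was not tested. Of 5799 genes 74 were at least 2-fold higher and 68 lower in APP/PS1 hippocampus; in APP/PS1-ApoeKO these were 115 and 234 of 5975, and 52 and 111 with the 165 further cells. Tested over the 4 sums with genotype as a block, edgeR called 0 of 16552 genes, and DESeq2 called 152 (89 higher, 63 lower). By edgeR 506 genes had an unadjusted p under 0.05, fewer than that limit passes with no effect. The homeostatic list rose by camera (median log2 fold change 0.20, 15 of 15 positive, adjusted p = 3.56e-08; adjusted p = 0.748 with an estimated correlation), with Olfml3 at 0.41 (SE 0.15, edgeR adjusted p = 1). The activated list fell (-0.43, 13 of 15 negative, adjusted p = 3.33e-07; adjusted p = 0.748 with an estimated correlation), with Cst7 at -1.08 (SE 0.32, edgeR adjusted p = 1). No list had a gene that passed when adjusted over the list alone, where the smallest adjusted p by edgeR was 0.115. In simulated data edgeR recovered 37 of 66 genes changed 8-fold for this contrast.

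Cells were grouped into states by clustering. Activated-like cells, clustered without the activated markers and without the genes shared by the knockout comparisons, made up 20.9% of APP/PS1 cortex (65 of 311 cells, exact binomial 95% interval 16.5 to 25.8) and 11.4% of APP/PS1 hippocampus (31 of 273, 7.85 to 15.7). They made up 1.78% of APP/PS1-ApoeKO cortex (3 of 169, up to 5.10), 2.80% of its hippocampus (9 of 321, 1.29 to 5.26), 0.614% of C57BL/6 cortex (2 of 326, up to 2.20) and 0.319% of C57BL/6-ApoeKO cortex (1 of 313, up to 1.77). That clustering was chosen after seeing the data; on all variable genes the shares in these groups were 19.9%, 12.1%, 1.78%, 2.80%, 0.614% and 0.319%. With cells thinned to 100000 reads they were 24.1%, 12.9%, 1.78%, 3.76%, 0.920% and 0.974%. A score of the activated markers per cell, with its limit at the 95th percentile of C57BL/6 cortex, placed 34.4% of APP/PS1 cortex and 23.7% of APP/PS1-ApoeKO cortex cells above it, and 15.4% and 16.5% in hippocampus; this is a range and not a type, with 49, 45, 22 and 63 cells within 10% of the limit. It was 5.21% in C57BL/6 and 12.1% in C57BL/6-ApoeKO, with 40 and 53 such cells.

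**Figure D4:**
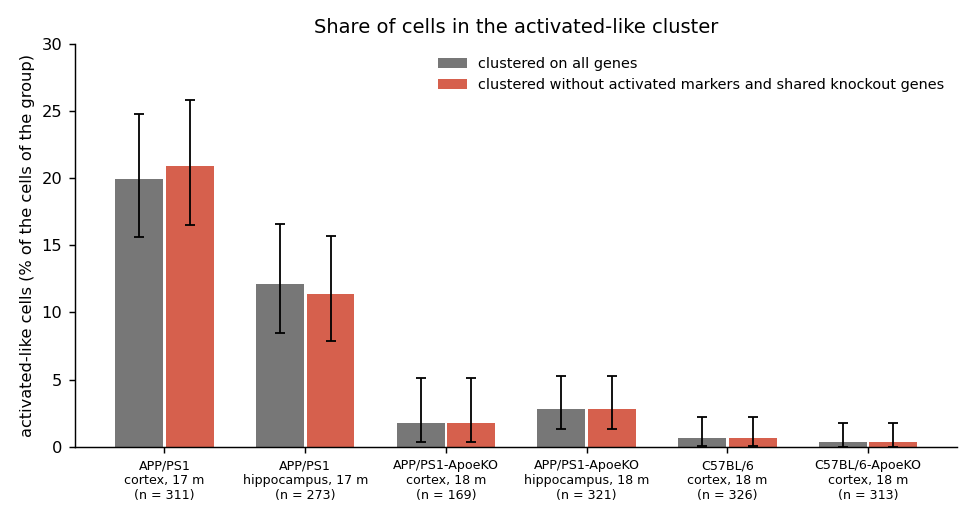
Percent of the cells of each group in the activated-like cluster, clustered on all variable genes (gray) and without activated markers and shared knockout genes (red); bars start at 0, and error bars are exact binomial 95% intervals of 1 sample per group. APP/PS1 cortex stands at 19.9% and 20.9%, and APP/PS1-ApoeKO cortex at 1.78% in both.

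Cells with reads of at least 3 interferon-response genes were 14.1% of APP/PS1 cortex (10.5 to 18.5), 13.6% of its hippocampus, 21.3% (15.4 to 28.3) and 21.8% (17.4 to 26.7) of APP/PS1-ApoeKO cortex and hippocampus, 4.91% (2.83 to 7.85) of C57BL/6 and 15% (11.2 to 19.5) of C57BL/6-ApoeKO cortex. Cells with at least 3 MHC class II genes were 10.3%, 7.69%, 2.96%, 6.54%, 6.75% and 6.71% of the groups in that order, not thinned for depth. Few cells carried markers of other cell types: at least 3 B cell, T or NK cell, or endothelial or mural markers were read in 0 cells of every group, which allows up to 1.34% (2.16% in APP/PS1-ApoeKO cortex). Monocyte, border-associated macrophage, astrocyte, oligodendrocyte, neuron and neutrophil markers were read in at most 3 cells of a group. Every cell had reads of at least 3 homeostatic microglial markers.

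The remaining lists lay inside the middle 95% of random lists in all 7 comparisons of 1 sum against 1 for cholesterol synthesis, complement, immediate early and dissociation, phagocytic receptors, TGF-beta signalling, respiratory chain and Alzheimer risk loci, although single members differed: C5ar1, a complement receptor, was 2.74-fold lower in APP/PS1 than in C57BL/6 cortex, and the immediate early gene Junb 3.02-fold (2.94 to 3.10) higher in APP/PS1-ApoeKO than APP/PS1 cortex. The cell cycle list was also low for the knockout in APP/PS1 cortex (-1.58, percentile 1.53, and -2.41 with the floor of 3 reads). Outside the random range in 1 comparison each lay the neuron, oligodendrocyte and astrocyte lists. The neuron list stood at -1.49 for hippocampus against cortex in APP/PS1-ApoeKO (percentile 1.25). With the floor of 3 reads it stood at -4.20, as 2 of its 4 members had no reads in 1 group. The oligodendrocyte list stood at -1.18 for amyloid without Apoe (percentile 1.80). The astrocyte list was higher for hippocampus against cortex in APP/PS1 (percentile 99.99), with medians of 0.97 and 0.07 within the 2 lanes.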

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

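Of the tests given here, those on carry-over, on clusters without activated and shared knockout genes, on DNA near Apoe, on DNA of another strain and on the mix of states, and the kind of interval for differences of shares, were chosen after the result was seen.

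In 6 cases the effect of a contrast lay beyond random lists in opposite directions in 2 groups. These are not 6 separate findings. The 2 glycolysis cases are 1 double difference of the same cortex sums. The 2 cytokine cases are 1 double difference of the same APP/PS1 and APP/PS1-ApoeKO sums. The difference was not tested in any of them. Beside each stands the SD of the list's median over pairs of the well parts called plates. These parts are not physical plates, so the SD is a spread between sets of wells and not between plates. For the Apoe knockout in APP/PS1, inflammatory cytokine genes had a median log2 ratio of -0.5578 in cortex (SD 0.348) and 0.9395 in hippocampus (SD 0.839). For the Apoe knockout in cortex, activated genes stood at -1.8925 in APP/PS1 (SD 0.404) and 0.4137 in C57BL/6 (SD 0.229), and glycolysis genes at -0.2268 (SD 0.116) and 0.4176 (SD 0.239). For amyloid in cortex, MHC class II genes stood at 2.332 with Apoe (SD 0.415) and -0.5323 without it (SD 0.546), and glycolysis genes at 0.4027 (SD 0.171) and -0.2533 (SD 0.145). For hippocampus against cortex, cytokine genes stood at -0.7702 in APP/PS1 (SD 0.551) and 0.7948 in APP/PS1-ApoeKO (SD 0.726). Some of these medians shrank or changed sign in homeostatic-like cells. Such cells leave out clusters 2, 5 and 6. Unnamed cluster 2 held 108 C57BL/6 cells and 26 APP/PS1 cortex cells, so contrasts with C57BL/6 can also change for that reason. The leading genes of clusters 5 and 6 include activated markers, MHC class II genes and the cytokine Ccl3. Smaller medians of such genes therefore follow from the choice of cells, which is no check of the direction. In homeostatic-like cells the knockout medians in APP/PS1 cortex were 0.58 for cytokines and -0.001 for activated genes, the amyloid medians with Apoe 0.26 for MHC class II and 0.09 for glycolysis, and the cytokine median for hippocampus against cortex in APP/PS1-ApoeKO -0.19; clusters 0 and 3 held most such cells of the knockout groups, cluster 1 those of APP/PS1 and clusters 4 and 1 those of C57BL/6. Without plate 1 the activated median for the knockout in C57BL/6 was 0.0862. The amyloid and knockout contrasts with a C57BL/6 arm share that group as their control, so its own departures enter both with the same sign. APP/PS1 cortex enters the amyloid contrast with Apoe and the knockout contrast in APP/PS1 cortex with opposite sign.

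Fewer activated-like cells were found in APP/PS1-ApoeKO than in APP/PS1 cortex, by 18.2 percentage points. A difference in reads per cell is argued against as the cause, since with all cells thinned to 100000 reads the difference was 22.3 points (16.8 to 27.5). Clusters driven by the activated markers and the 77 shared knockout genes alone are argued against. Without these genes the difference was 19.1 points (13.8 to 24.1). Other genes that differ with the knockout were kept, among 538 at least 2-fold higher and 184 at least 2-fold lower in cortex. Clusters driven by those genes stay open. Clusters that follow Apoe-linked genes and not the state are argued against as the whole source, since the share above the limit of the marker score, which holds no Apoe, differed the same way in cortex by 10.7 points (2.14 to 18.7); these intervals count cells of 1 sample per group. In hippocampus this explanation stays open, because 15.4% of APP/PS1 and 16.5% of knockout cells lay above the limit; in knockout cortex 7.5% of the cells above it were activated-like, and 45 cells lay within 10% of it against 40 above. Lane and age are confounded with genotype, so a biological effect of Apoe loss remains an untested hypothesis.

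The 77 genes that were at least 2-fold apart the same way in all 3 knockout comparisons, Trim12a, Scoc, Bst2 and Sorl1 among them, might come from DNA carried along with the targeted Apoe allele. DNA beside Apoe is argued against as the whole source, since 1.32% of those with a position lay within 20 Mb of Apoe (1 of 76, upper bound 7.11%). A different mix of the states that clusters resolve is argued against as the whole source, within the part of the mix that both groups share. Both groups were given the same mix of clusters made without these genes. In APP/PS1 cortex, APP/PS1 hippocampus and C57BL/6 cortex, 2, 4 and 6 clusters held enough cells. The shared part of the mix was 0.276, 0.355 and 0.644 in that order, and cells outside it were not matched. The median log2 ratio of the genes was then 1.04 times that in all cells (0.938 to 1.25). In the same order it went from 2.27 to 2.73, from 2.55 to 2.32 and from 1.76 to 1.83. In APP/PS1 cortex, where 60 knockout and 71 APP/PS1 cells entered, 71 of 77 genes kept their direction. All 77 kept it in the other comparisons. DNA of another strain elsewhere in the genome could not be told apart from other sources: 33 of the genes had another within 5 Mb, inside the range of random sets (16 to 36; 992 of 10000 sets had as many), whereas within 1 Mb there were 22 against a random range of 2 to 17 (22 of 10000 sets). The loss of Apoe itself, and other differences between the mouse lines, stay open as untested.

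Apoe reads in the C57BL/6-ApoeKO cells, 0.611% of the level in C57BL/6 (0.563 to 0.663), might have been carried over from C57BL/6 wells of the same lanes. Of 5 genes read in C57BL/6 and not in the knockout cells of other lanes, 3 had an upper bound under 0.5 of the ratio of Apoe: Colec12, Mxra8 and Shroom4 had 0 reads in C57BL/6-ApoeKO against 9018, 12401 and 12649 in C57BL/6 (upper bounds 0.0497%, 0.0362% and 0.0355%). The other 2, Apob and Ifi44, stood at 16.3% and 14.0%, above the ratio of Apoe. Carry-over shared by all genes is thereby argued against. A few misplaced or mixed wells stay open, since 582 of the 589 Apoe reads were in 2 cells.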

How the results depend on the processing

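The fit of all 6 sums, all cells of the table, reads without ribosomal and mitochondrial RNA and the clustering without marker and shared knockout genes were chosen after seeing the data. No paired analysis was possible because the labels' numbers are plates and wells and name no animals; genotype already blocks the tissue contrast. Alternatives that left 0 residual degrees of freedom, and activated-like cells alone, gave no value. Of the list medians under all alternatives, 1213 stayed within 1 SD over pairs of the well parts called plates, 100 moved and 10 changed sign from outside the random range. Sign changes of any size were 129: 90 within that SD, 29 beyond it in lists inside the random range, and these 10. Of named genes 522 stayed, 37 moved and 1 changed sign, of state shares 100 stayed inside the interval and 28 moved, and of 2-fold counts 50 stayed within 1.5 times and 6 moved. The cause was not tested in any case below. Depth limits the knockout cortex most, with 74767907 reads and 1 lane.

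The counts of called genes were 0 by edgeR with RLE factors, without a filter, in homeostatic-like cells and in all cells, and 0 by limma. DESeq2 called 152 genes for tissue, 301 for amyloid and 548 for the Apoe knockout, and with all 6 sums 201, 357 and 1027, where edgeR called 0, 0 and 5. In data simulated at the spread of the real sums, DESeq2 made more false calls than edgeR. The list calls all fell to 0, 0 and 0 with an estimated correlation, 14 calls in all.

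The activated median moved most in homeostatic-like cells: -0.001 for the knockout in APP/PS1 cortex, 0.19 in hippocampus, where its sign changed, 1.17 for amyloid with Apoe and -0.52 for hippocampus against cortex in APP/PS1. Those cells leave out the activated-like cluster, which was named from the activated markers, and the unnamed and interferon-response-like clusters. A smaller activated median there therefore follows from the choice of cells. It does not show where the difference lay and is no check of it. In all cells of a group, the median moved less. The activated median was -1.29 for the knockout in APP/PS1 cortex with all cells of the table, and 0.0862 in C57BL/6 without plate 1. It was 2.22 for amyloid with Apoe with 5 RPM added, and 0.11 for amyloid without Apoe without plate 3. Cytokine medians changed sign in homeostatic-like cells for the knockout in APP/PS1 cortex (0.58) and for hippocampus against cortex in APP/PS1-ApoeKO (-0.19, and -0.16 without plate 1), without plate 3 for the knockout in C57BL/6 (0.33), and without plate 1 for amyloid with Apoe (-0.018). MHC class II in homeostatic-like cells was -0.12 and -0.67 for the knockout in APP/PS1 cortex and hippocampus and 0.26 for amyloid with Apoe, where lysosome stood at 0.13 (-0.08 for the knockout in APP/PS1 cortex), and changed sign for hippocampus against cortex (-0.19 in APP/PS1, -0.0695 in APP/PS1-ApoeKO). The interferon median for hippocampus against cortex in APP/PS1 was -0.0427 with each cell scaled to the same total before summing and -0.11 without plate 2. Without plate 4 it was -0.16 for the knockout in APP/PS1 cortex and -0.03 for amyloid without Apoe, both sign changes, and in homeostatic-like cells 0.91 for the knockout in C57BL/6. Lpl, higher with amyloid in all cells, had a log2 ratio of -0.28 in homeostatic-like cells.

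With all cells, 119 genes were at least 2-fold lower for the knockout in APP/PS1 cortex, 108 higher and 65 lower for amyloid without Apoe, and 52 higher and 111 lower for hippocampus against cortex in APP/PS1-ApoeKO; in homeostatic-like cells 113 were higher for that contrast in APP/PS1. The genes chosen by amyloid at 3-fold had a median of -0.53 in knockout hippocampus.

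The activated-like share of APP/PS1 cortex was 26% with 30 components. At resolution 0.4 it was 5.33% in APP/PS1-ApoeKO cortex, 6.85% in its hippocampus and 2.24% in C57BL/6-ApoeKO, which also had 2.24% with 30 components. Above the limit of the score were 34.4% of APP/PS1 cortex, 23.7% and 16.5% of APP/PS1-ApoeKO cortex and hippocampus, 5.21% of C57BL/6 and 12.1% of C57BL/6-ApoeKO cells. By the well parts called plates, APP/PS1-ApoeKO hippocampus had 5.66% on plate 1 and 1.08% on plate 4. C57BL/6 had 0% on plates 1 and 4, and C57BL/6-ApoeKO had 1.82% on plate 1 and 0% on plates 2, 3 and 4.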

Other observations

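The values here were picked after they were seen. Tfrc, the transferrin receptor that takes up iron, was 68.6-fold (65.2 to 72.3) higher in APP/PS1-ApoeKO than in APP/PS1 cortex and 45.1-fold (43.3 to 47.0) higher than in C57BL/6-ApoeKO cortex, and 3.88-fold (3.82 to 3.95) lower in hippocampus than in cortex of APP/PS1-ApoeKO. Gpnmb, a lysosomal glycoprotein of foamy macrophages, was read at 30.5 RPM in APP/PS1-ApoeKO hippocampus, yet in 0.312% of its cells, and at most 0.503 RPM elsewhere. Lpl reached 147 RPM in the same group in 4.05% of cells. The level of Gpnmb in that group thus came from 1 cell.

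C57BL/6 cortex stood apart from the 5 other groups in genes outside the fixed lists. Spint1 had 0 reads there, against 151 and 139 RPM in APP/PS1 cortex and hippocampus, 211 and 208 RPM in those of APP/PS1-ApoeKO and 240 RPM in C57BL/6-ApoeKO cortex. Shroom4, a cytoskeletal protein, had 52.4 RPM in C57BL/6 and 0 reads in the other groups, and the chemokine receptor Ccr6 was 294-fold (224 to 395) lower in APP/PS1 and 62.1-fold (54.9 to 70.6) lower in C57BL/6-ApoeKO cortex, with 79.7 RPM in C57BL/6 and at most 8.41 RPM (APP/PS1 hippocampus) elsewhere.

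The 165 APP/PS1-ApoeKO cortex cells that the labels give no depth for entered the comparisons as an alternative alone. Clustered with all other cells, 6 of them (3.64%, 1.35 to 7.75) were activated-like and 11 (6.67%, 3.37 to 11.6) interferon-response-like, against 4 (2.37%) and 9 (5.33%) of the 169 cells of the other lane. Their median cell held 416147 reads and 2362 genes.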
